A study of Mus musculus with 6 samples.

How the data were processed

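HCFC1 occupancy was measured by ChIP-seq in Hepa1-6 mouse hepatoma cells under 3 siRNA conditions (control, ERRα and HCFC1). Per the labels' protocols, siRNA was given at 100 nM and again after 48 h, which the sample labels total as 200 nM over 96 h. The labels name 6 libraries, an HCFC1 and an IgG immunoprecipitation for each condition. Each HCFC1 list stands for 1 library, and a note deposited with the lists says that 2 independent immunoprecipitations were pooled before sequencing. The IgG libraries were not analysed here, and how they entered peak calling is not given in the sources used here.

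The starting point was the authors' deposited list of annotated peaks for each HCFC1 library. The submitters' processing notes name BWA 0.7.12, Picard 2.0.1, MACS2 2.1.1.20160309, HOMER 4.11.1 and the mm10 build, without saying which step each served. Each deposited peak has a chromosome, a start, an end, a score, an annotation, a distance to the nearest transcription start and a gene. The peak score was deposited by the authors as whole numbers from 13 upwards in every list. Its scale is not stated, so it was used only to describe, rank, bin or filter peaks within a list. Start and end positions are printed as the authors gave them. Read numbers were not part of the lists, so sequencing depth is unknown and part of any difference in list length could not be separated from depth. The deposited distance to a transcription start is measured from the centre of a peak: for 3404 of 3529 genes with 1 control and 1 ERRα-knockdown peak (96.5%), the distances differed by as much as the centres did, within 1 bp. The place label probably follows the centre too, in which case a wide peak that reaches into a promoter can carry another label.

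A control peak was counted as kept when at least 1 bp of a peak in a knockdown list overlapped it. Background overlap was measured by shifting the subject list along each chromosome by a random distance, 100 times. Shares carry exact binomial (Clopper-Pearson) 95% intervals, which cover counting error only. With 1 library per condition there was no replicate spread, so no p-value was computed. Control peaks missing from both knockdown lists were compared with independent loss, as n1 × n2 / N and within 20 equal bins of control score, with 10000 draws. For the shares kept by score, the 36147 control peaks were put in 10 equal bins.

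Genes were matched by gene identifier to the mouse RefSeq gene table of the same build. The table held 14405 of 14421 identifiers in the control list (99.9%), 12579 of 12587 in the ERRα-knockdown list and 8774 of 8783 in the HCFC1-knockdown list. A gene had a promoter peak when a peak annotated to a promoter was assigned to it. Its score was that of its highest-scoring promoter peak. The count of kept genes was set in advance as genes with a promoter-annotated peak in the knockdown list. A second count, by overlap of any control promoter peak of the gene with any knockdown peak, was added after the data were seen. Each list's share was placed as a percentile among 10000 random lists with the same number of genes in each of 20 score bins, as a description of these libraries only.

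The 21 gene lists were oxidative phosphorylation, pyruvate dehydrogenase and TCA cycle, fatty acid oxidation, mitochondrial ribosome, cytosolic ribosome, DNA replication and cell cycle, ribosome biogenesis, aminoacyl-tRNA synthetases, proteasome, mitochondrial DNA expression and import, ERRα targets and partners, HCFC1 partners, cobalamin metabolism, cholesterol and fatty acid synthesis, hepatocyte identity, the amino acid and integrated stress response, the circadian clock, and markers of neurons, immune cells, muscle, and endothelial, stellate and biliary cells. The lists, the comparisons, the tests, the rule for named genes and the alternatives not described as added were fixed before the data were examined. The rule named every peak assigned to Hcfc1 and Esrra, and the 10 control promoter peaks with the highest score. For each knockdown it named the 10 strongest control promoter peaks without an overlapping peak and the 10 strongest knockdown peaks without a control peak. In each gene list it took up to 4 members with the highest control promoter score, and up to 4 such members lacking a promoter-annotated peak in each knockdown list; the text gives a part of these, and some genes the rule names are not reported here.

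The alternatives were a reciprocal overlap of at least 50%, peak centres within 200 bp, the higher-scoring 50% of the query list or of every list, lists of equal length, merging of peaks within 500 bp, chromosomes 1 to 19 and X only, 10 or 50 score bins, and promoters defined by a distance to the nearest transcription start of at most 1000 or 5000 bp. Added after the data were seen were a score of at least 100, score bins split by promoter annotation, chromosome or peak width, and the overlap count of kept genes. A planned search for transcription factor motifs was not run because no genome sequence was used here.

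The functions were tested on simulated data. All 4500 overlap calls matched a direct comparison of every pair of peaks. For the count of peaks missing from both lists, 36147 simulated peaks lost independently gave a ratio of observed to score-matched counts of 1.00 on average over 20 simulations. A shared loss of 10% of the peaks gave 1.01 or more in each of 20. For gene lists, 200 random lists of 30 among 5567 genes fell outside the central 95% in 4.0% of cases, and 94.5% of lists that had lost 50% of their kept genes fell under percentile 2.5. Most of the lists used here had fewer than 30 genes with a control promoter peak, and smaller lists were not simulated. Python 3.11.15 was used with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.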

Results

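HCFC1 (host cell factor C1) is a chromatin coregulator that reaches promoters through DNA-binding partners such as THAP11 and ZFP143. ERRα, encoded by Esrra, is an orphan nuclear receptor known for its control of mitochondrial and energy metabolism genes. The positions of HCFC1 were mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in Hepa1-6 cells, a mouse hepatoma line. Before the assay, cells received control small interfering RNA (siRNA), siRNA against ERRα or siRNA against HCFC1, at 200 nM in total over 96 h. The data set held 6 libraries, 3 made with an HCFC1 antibody and 3 with IgG, which gives 1 HCFC1 library for each of the 3 conditions. Each HCFC1 library pooled 2 independent immunoprecipitations. With 1 list per condition, no difference described here has a replicate check. The read depth behind each list is unknown. All positions are on the mm10 build.

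The lists held 36147 HCFC1 peaks in control cells, 21881 after ERRα knockdown and 12610 after HCFC1 knockdown. Peaks in the ERRα-knockdown list were wider, with a median of 710 bp against 393 bp in control and 465 bp after HCFC1 knockdown. As a result, the ERRα-knockdown list covered about as much of the genome as the longer control list, 22.8 Mb against 22.3 Mb, while the HCFC1-knockdown list covered 8.29 Mb. The peak scores are the authors' own and were used only to describe, rank, bin or filter peaks within a list. The lowest score was 13 in each list, and the median was 35 in control, 59 after ERRα knockdown and 36 after HCFC1 knockdown.

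Promoters made up a larger part of both knockdown lists than of the control list. In control cells 5787 peaks (16.0%, exact binomial 95% interval 15.6 to 16.4%) were annotated to a promoter. The share was 24.6% (5375 peaks, 24.0 to 25.1%) after ERRα knockdown and 28.9% (3638 peaks, 28.1 to 29.7%) after HCFC1 knockdown. Intergenic peaks went the other way, from 29.2% (10567 peaks) in control to 14.5% (3167 peaks) and 12.5% (1580 peaks). Introns held 38.1% of control peaks, 35.0% after ERRα knockdown and 32.1% after HCFC1 knockdown. Intervals cover counting error only. When every list was shortened to its 12610 highest-scoring peaks, the promoter share was 33.2% in control, 35.6% after ERRα knockdown and 28.9% after HCFC1 knockdown, so the order depended on list length.

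**Figure D1:**
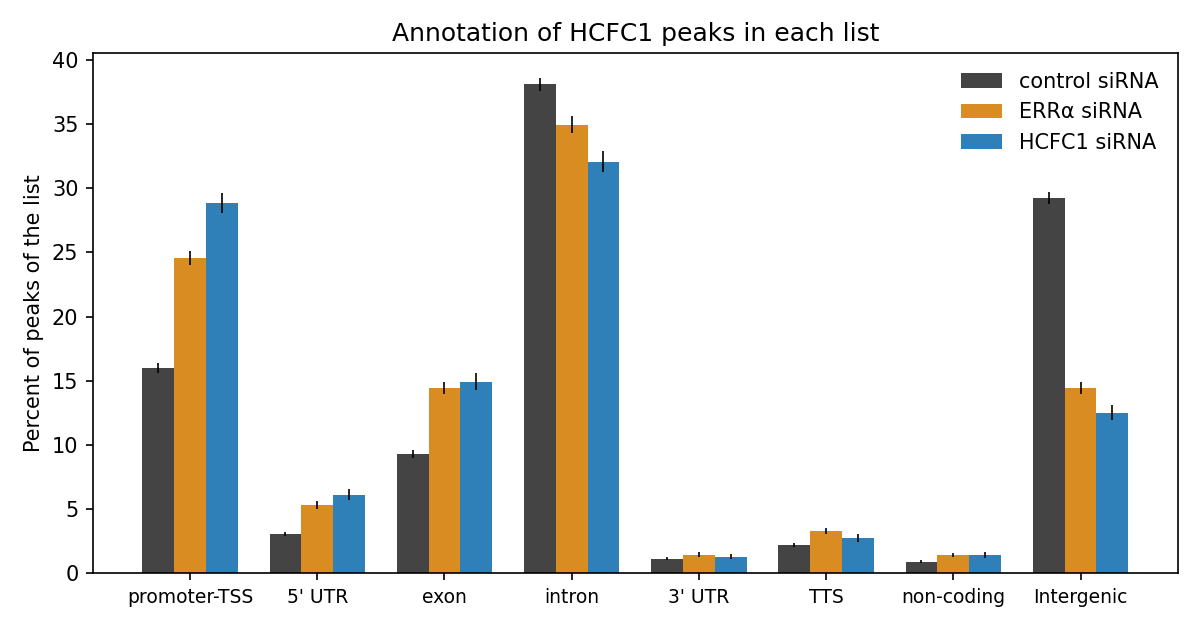
Percent of HCFC1 peaks (vertical axis) in each class of the deposited annotation (horizontal axis) for the control, ERRα-knockdown and HCFC1-knockdown lists, 1 list each; error bars are exact binomial 95% intervals and cover counting error only. Promoter peaks were 16.0% of the control list, 24.6% after ERRα knockdown and 28.9% after HCFC1 knockdown, and intergenic peaks 29.2%, 14.5% and 12.5%.

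The strongest promoter peaks of control cells lay at genes of varied function. The highest score, 30879, belonged to the pseudogene Pisd-ps3 on the unplaced contig JH584304 (58353 to 61425). It was followed by Btrc, a ubiquitin ligase substrate receptor (chromosome 19, 45361757 to 45365056, score 12412), and by Maf1, a repressor of RNA polymerase III (chromosome 15, 76349612 to 76354488, score 11070). Hsph1, a heat shock protein gene, had a score of 10375 (chromosome 5, 149635231 to 149637750). Eny2, a transcription and mRNA export factor, had a score of 10302 (chromosome 15, 44425645 to 44428795). Katnal1 (9780), the kinase gene Gsk3a (9730), the nuclear pore gene Ndc1 (9277), Dus3l (9255) and Ctdp1 (9003) completed the 10 highest. All 10 peaks were overlapped by a peak in each knockdown list.

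Of 21900 protein-coding genes, 23.5% (23.0 to 24.1%) had a control promoter peak, and most housekeeping and metabolic lists had a larger share. These shares depended on the promoter label. With promoters set by a distance of at most 1000 bp, the share of all genes was higher. By that rule 34 of 61 list values, occupied or kept, left their interval. The label also counted Esrra as unoccupied, although a control peak was centred 191 bp from a transcription start. The proteasome list had a smaller share (19.4%, 7.45 to 37.5%). Its interval and that of the ERRα targets and partners (27.6%, 12.7 to 47.2%) both included 23.5%. Cobalamin metabolism had the highest share among the 21 lists, with 10 of 15 genes (66.7%, 38.4 to 88.2%), led by the vitamin B12 processing gene Mmachc at a score of 7836. The circadian clock list followed with 14 of 22 genes (63.6%), and ribosome biogenesis with 19 of 30 (63.3%), where Wdr12 scored 4345 and Nop14 3137. Fatty acid oxidation had 13 of 23 genes, HCFC1 partners 14 of 28, cholesterol and fatty acid synthesis 14 of 28, and the amino acid and integrated stress response 12 of 25. The pyruvate dehydrogenase and TCA cycle list had 10 of 21 genes, with Suclg1, a subunit of succinyl-CoA ligase, at 3219. Mitochondrial DNA expression and import had 13 of 28 genes, among them the protease gene Clpp (2843) and the mitochondrial RNA polymerase gene Polrmt (2158).

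The ribosomal and respiratory lists had the largest numbers of occupied genes. The cytosolic ribosome had 34 of 76 genes with a control promoter peak (44.7%, 33.3 to 56.6%), with Rpl7 at 4121 and Rplp2 at 3424. The mitochondrial ribosome had 31 of 76 (40.8%), with Mrpl34 at 3383 and Mrpl42 at 2437. Oxidative phosphorylation had 31 of 75 (41.3%, 30.1 to 53.3%), with the complex I gene Ndufb5 at 5915 and the complex III gene Uqcr10 at 3197. DNA replication and cell cycle had 20 of 45 genes, with Cdc45 at 1696 and Mcm3 at 1392, and the aminoacyl-tRNA synthetases had 15 of 37, with Fars2 at 1988. The ERRα targets and partners had 8 of 29 (27.6%), led by the mitochondrial fusion gene Mfn2 (3762) and Gabpa (1228), and the proteasome 6 of 31 (19.4%), led by Psma2 (2447).

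Tissue-restricted lists had lower shares than the 23.5% of all protein-coding genes, but only the interval of the immune markers excluded that value. Hepatocyte identity had 6 of 38 genes (15.8%, 6.02 to 31.3%), with Cebpb at 121 and Foxa2 at 56. Neuronal markers had 2 of 20 genes (Tubb3, 70, and Slc17a7, 62), the endothelial, stellate and biliary markers 2 of 19 (Sox9, 59, and Krt7, 27), and muscle markers 1 of 16 (Myog, 40). None of the 20 immune markers had one (0%, 0 to 16.8%).

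The HCFC1 knockdown was planned as a check of the antibody and of the labels, since less HCFC1 should leave fewer peaks. Depth is unknown and the ERRα-knockdown list was also shorter than the control list, so list length alone cannot decide this. Neither RNA nor protein levels were analysed here, so the extent of either knockdown is not known. The HCFC1-knockdown list had 34.9% as many peaks as the control list, and the ERRα-knockdown list 60.5%. The control promoter peak of Hcfc1 (chromosome X, 73965347 to 73968142, -387 bp from the transcription start) had a score of 1924 and ranked 256 of 5787 control promoter peaks. All 255 promoter peaks with a higher score were overlapped in the HCFC1-knockdown list, and the Hcfc1 peak was not. Chromosome X as a whole kept few promoter peaks in that list, 27 of 90 (30.0%). That share covers peaks of every score, while the next missing promoter peak on any chromosome, of Rpl13a, ranked 720 (score 745). Chromosome X peaks of similar score were not compared, so whether the loss is particular to the gene is not settled. A weaker control peak in intron 1 of Hcfc1 (73964094 to 73964960, score 76) was absent from that list too. The ERRα-knockdown list held a peak across both positions (73964278 to 73968072, score 2760). The Esrra gene had weaker control peaks, at chromosome 19, 6921043 to 6922192 (score 125), and over exon 2 (6919966 to 6920659, score 34). Both were overlapped by an ERRα-knockdown peak (6919909 to 6922524, score 96), and the first also by a narrow peak after HCFC1 knockdown (6921303 to 6921566, score 13).

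**Figure D2:**
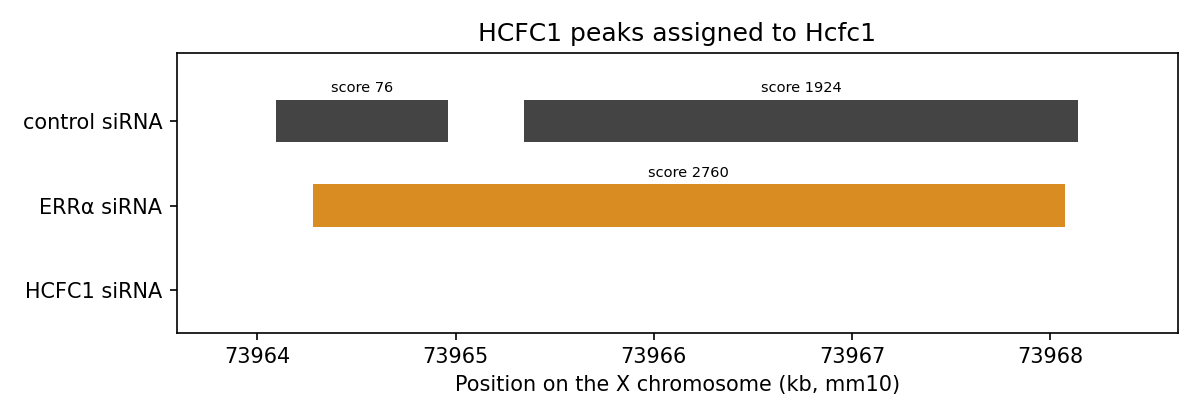
Positions of the HCFC1 peaks assigned to Hcfc1 on the X chromosome (horizontal axis, kb, mm10) in the control, ERRα-knockdown and HCFC1-knockdown lists, drawn as bars to scale with the authors' scores. The control list had peaks with scores 1924 and 76, the ERRα-knockdown list had a peak with score 2760, and the HCFC1-knockdown list had none.

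After HCFC1 knockdown, most peaks of the full control list had no counterpart, and promoter peaks were kept more often than others. Of the 36147 control peaks, 8045 (22.3%, 21.8 to 22.7%) were overlapped by at least 1 bp of a peak in the HCFC1-knockdown list. The share was 55.6% (3218 of 5787, 54.3 to 56.9%) at promoters, 15.9% elsewhere and 4.73% in intergenic regions. Shifting the knockdown peaks along their chromosomes gave 0.766% on average over 100 shifts. Among promoter peaks in 10 bins of control score, the kept share was between 10.9% and 19.1% in the 6 lowest bins, without a steady rise, and then rose from 34.0% in the next to 91.9% (1770 of 1927) in the highest. With reciprocal overlap of at least 50% the promoter share fell to 31.4%. The share of all control peaks depended on their score and on list length: it was 51.1% with lists of equal length and 78.9% of control peaks with a score of at least 100, a limit chosen after the data were seen. With that limit in the HCFC1-knockdown list too, the share was far lower, as given with the alternatives below.

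After Hcfc1, the strongest control promoter peaks missing from the HCFC1-knockdown list were those of the ribosomal protein gene Rpl13a (chromosome 7, 45127834 to 45130489, score 745), the zinc finger gene Zfp617 (chromosome 8, 71921987 to 71923351, score 704), Caml (chromosome 13, 55621872 to 55623570, score 684) and Uba1, the ubiquitin-activating enzyme gene (chromosome X, 20657660 to 20659242, score 634). Others among the 10 highest were 2210417A02Rik (618), Gm5129 (528), Dpysl5 (506) and Ubl7 (481). All 10 were overlapped in the ERRα-knockdown list.

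Retention after HCFC1 knockdown differed between gene groups, but no list of at least 6 genes lay outside the central 95% of score-matched lists. That range was wide for small lists, 0 to 66.7% for hepatocyte identity and 66.7 to 100% for the proteasome. Such lists could hardly leave it, so this does not show that the groups were kept alike. The control promoter peak was overlapped for 31 of 34 cytosolic ribosome genes, 25 of 31 mitochondrial ribosome genes, 13 of 15 aminoacyl-tRNA synthetases, 11 of 13 mitochondrial DNA expression and import genes, 11 of 14 HCFC1 partners and all 6 proteasome genes. It was overlapped for 22 of 31 oxidative phosphorylation genes, 13 of 19 ribosome biogenesis genes, 6 of 8 ERRα targets and partners, 11 of 20 DNA replication and cell cycle genes and 6 of 10 pyruvate dehydrogenase and TCA cycle genes. Lower shares were found for fatty acid oxidation (6 of 13; Decr1 and Eci1, both 157, not overlapped), cobalamin metabolism (5 of 10; Abcd4, 99, not overlapped) and cholesterol and fatty acid synthesis (5 of 14; Srebf1, 57, not overlapped). The amino acid and integrated stress response kept 6 of 12, without Ddit3 (137) and Asns (83), the circadian clock 7 of 14, without Clock (83) and Tef (60), and hepatocyte identity 1 of 6. The cell cycle regulator E2f1 (212), a member of 2 lists, was also without an overlapping peak. Among 10000 random lists matched on control score, these shares lay between percentile 14.3, for cholesterol and fatty acid synthesis, and percentile 82.5, for ERRα targets and partners.

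ERRα knockdown bears on whether HCFC1 positions depend on this receptor, but only within limits. The extent of the knockdown is not known, and no ERRα binding data were used here. Peaks in that list were also wider (median 710 bp against 393 bp in control), which makes a 1 bp overlap easier. The strongest HCFC1 promoter peaks were all present after ERRα knockdown, and the promoter peaks that went missing had lower scores. In all, 14673 control peaks (40.6%, 40.1 to 41.1%) were overlapped in the ERRα-knockdown list, including 5103 promoter peaks (88.2%, 87.3 to 89.0%), 31.5% of other peaks and 12.7% of intergenic peaks. Shifted positions gave 1.60% on average. In the highest of 10 bins of control score (178 and above) all 1927 promoter peaks were overlapped (100%, 99.8 to 100%). In the lowest bin 48.9% of promoter peaks were overlapped. With peak centres required to lie within 200 bp, the promoter share fell to 49.6%. With lists of equal length, 71.8% of control peaks and 95.4% of control promoter peaks were overlapped.

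**Figure D3:**
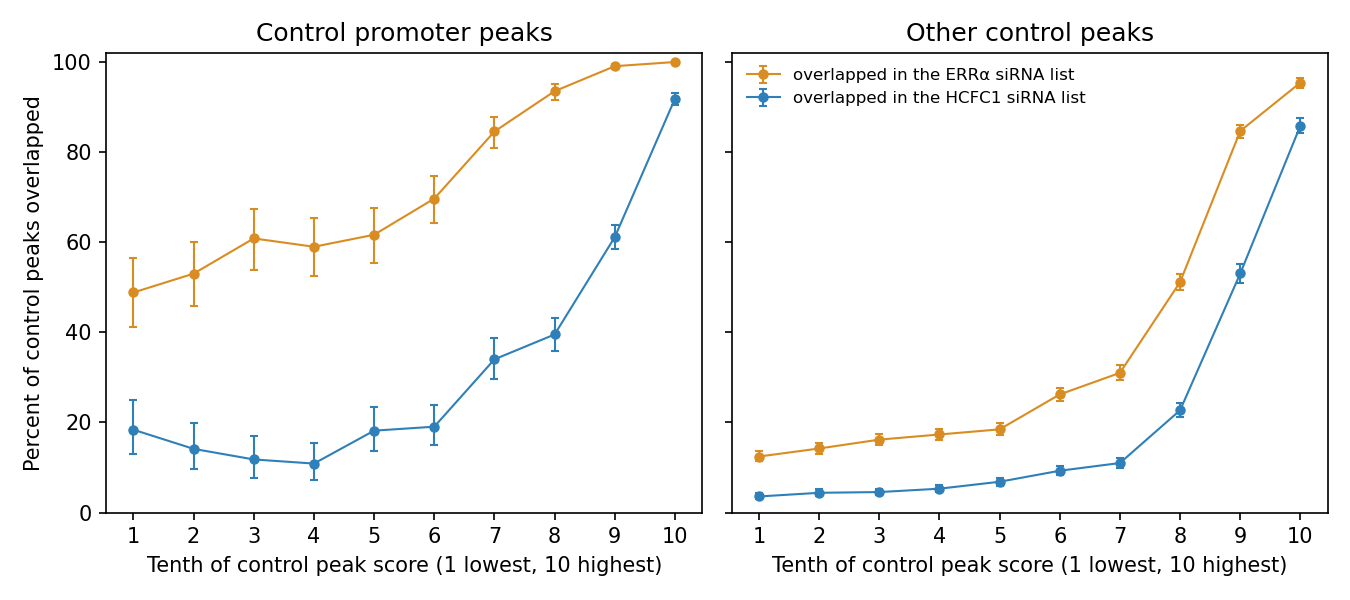
Percent of control peaks overlapped by at least 1 bp in the ERRα-knockdown or HCFC1-knockdown list (vertical axis) by bin of control peak score (horizontal axis, 10 equal bins, 1 lowest to 10 highest), for promoter peaks and for other peaks; points are shares in 1 list and error bars are exact binomial 95% intervals for counting error only. At promoters the shares went from 48.9% to 100% for ERRα knockdown and from 18.4% to 91.9% for HCFC1 knockdown.

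Only 4 of the 2833 control promoter peaks with a score of at least 100 had no ERRα-knockdown peak, a score limit chosen after the data were seen. They were Fam135b (chromosome 15, 71727323 to 71728463, score 131), Tm7sf2, which encodes a sterol reductase (chromosome 19, 6067928 to 6068464, score 106), the non-coding Gm5106 (chromosome 5, 8798124 to 8798813, score 100) and Sh3tc1 (chromosome 5, 35728932 to 35729563, score 100). The next were Arhgef39 (95), the neuronal transcription factor gene Npas1 (94), Borcs8 (92), the purine synthesis gene Adsl (91), Zfp51 (86) and Lipo2 (84). Of these 10, Fam135b, Gm5106 and Lipo2 were overlapped in the HCFC1-knockdown list.

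Of all genes with a control promoter peak, 89.0% (4952 of 5567) had such a peak overlapped after ERRα knockdown, by a count added after the data were seen. Below this share, among lists of at least 6 genes, lay hepatocyte identity (83.3%) and fatty acid oxidation (84.6%). DNA replication and cell cycle (85.0%) and cholesterol and fatty acid synthesis (85.7%) did too. All of them lay within their score-matched ranges, with matched means of 71.4%, 83.6%, 88.7% and 86.8% in that order. The planned count, given further below, put several metabolic lists under the share of all genes. Among them were pyruvate dehydrogenase and TCA cycle, fatty acid oxidation, and cholesterol and fatty acid synthesis. Their score-matched percentiles were 8.65, 11.1 and 30.9. Oxidative phosphorylation and cobalamin metabolism lay above the share of all genes. Against score-matched lists, however, oxidative phosphorylation was at percentile 29.6 (61.3% against a matched mean of 65.8%) and cobalamin metabolism at percentile 64.5. The control promoter peak was overlapped for all 31 oxidative phosphorylation genes, all 31 mitochondrial ribosome genes, all 13 mitochondrial DNA expression and import genes, all 8 ERRα targets and partners, all 14 HCFC1 partners, all 15 aminoacyl-tRNA synthetases, all 10 cobalamin genes, all 14 circadian clock genes and all 6 proteasome genes. It was overlapped for 9 of 10 pyruvate dehydrogenase and TCA cycle genes, all but Idh2 (52), and for 11 of 13 fatty acid oxidation genes, where Acsl1 (46) was among those without. The counts were 33 of 34 for the cytosolic ribosome, 18 of 19 for ribosome biogenesis, 17 of 20 for DNA replication and cell cycle, and 12 of 14 for cholesterol and fatty acid synthesis. For the amino acid and integrated stress response it was 11 of 12, without the proline synthesis gene Aldh18a1 (34), and for hepatocyte identity 5 of 6, without the gluconeogenic gene Pck1 (17). Among the small marker lists, both neuronal genes and both endothelial, stellate and biliary genes were overlapped, and the muscle gene Myog was not. By the same overlap count, the neuronal list kept 1 of 2 (Tubb3) after HCFC1 knockdown, and neither of the other lists kept any. Sox9, not overlapped there, did have a promoter-annotated peak in the HCFC1-knockdown list. For the 17 lists with at least 6 control promoter genes, score-matched percentiles of overlap after ERRα knockdown were compared. They lay between 27.8, for DNA replication and cell cycle, and 97.2, for the circadian clock. Matched means were already 97.6% for oxidative phosphorylation, 99.4% for the mitochondrial ribosome and 100% for the proteasome. Such lists could hardly exceed them, so their full counts do not show that these promoters were spared.

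**Figure D4:**
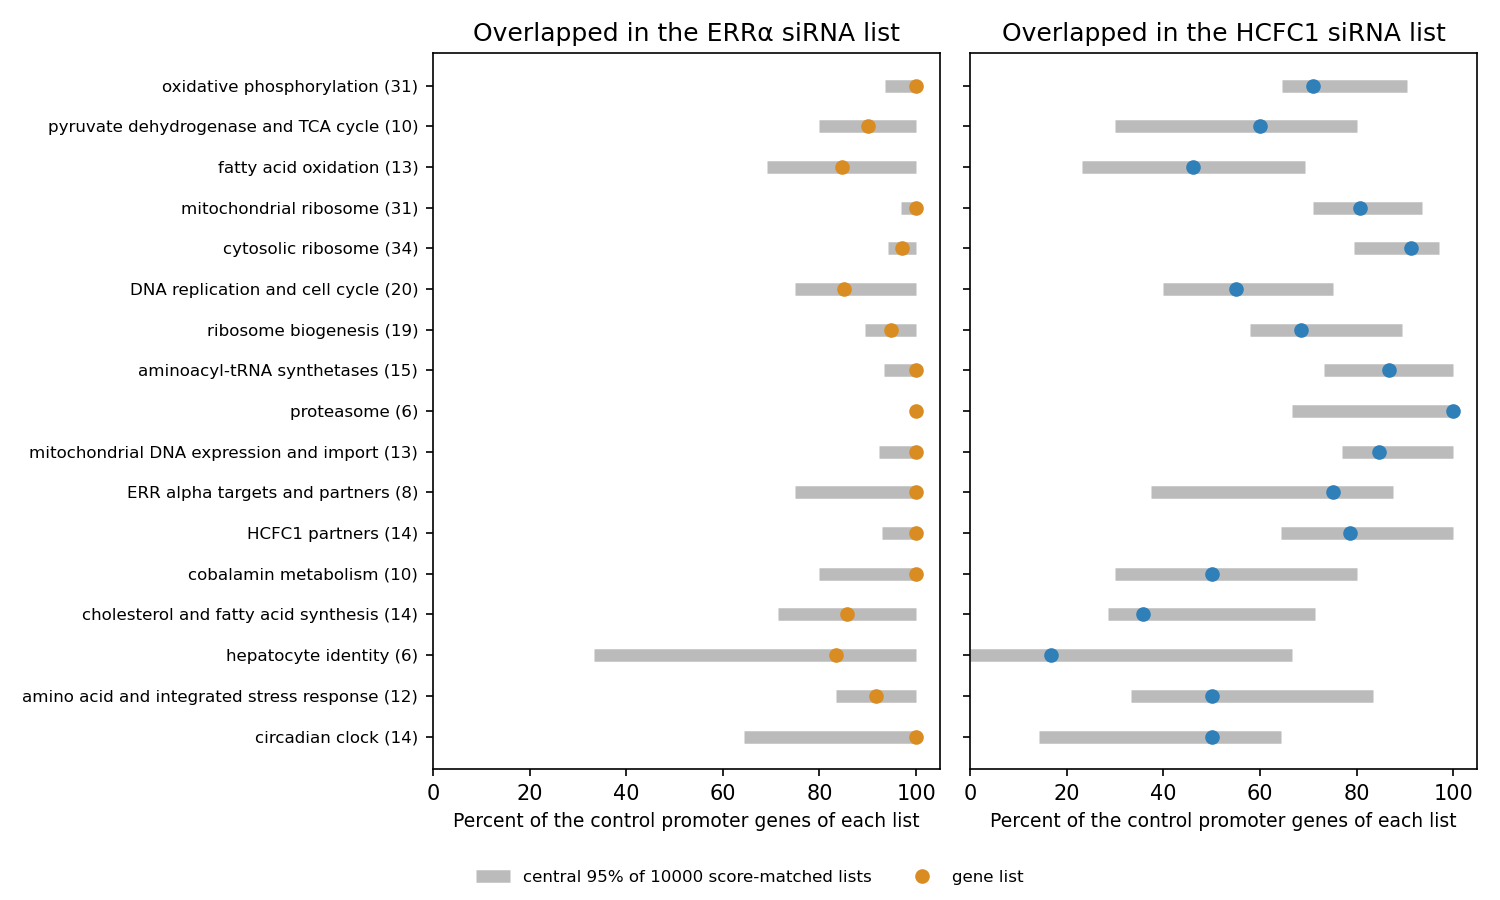
Percent of each list's genes with a control promoter peak (number in brackets) whose peak was overlapped in the ERRα-knockdown or HCFC1-knockdown list (horizontal axis); dots are the lists and grey bars the central 95% of 10000 random lists matched on control score. All 31 oxidative phosphorylation genes were overlapped after ERRα knockdown and 22 of 31 after HCFC1 knockdown, against score-matched means of 97.6% and 77.5%.

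A gene can also be counted as kept only when the knockdown peak itself is annotated to its promoter, the count set in advance. By that count 3302 of 5567 genes (59.3%) were kept after ERRα knockdown and 2233 (40.1%) after HCFC1 knockdown, against 4952 (89.0%) and 3179 (57.1%) by overlap, a measure added after the data were seen. The cytosolic ribosome kept 15 of 34 genes after ERRα knockdown by annotation (percentile 0.42 among score-matched lists) and 33 of 34 by overlap (percentile 29.3). Against the 59.3% of all genes, the shares were 40.0% for the pyruvate dehydrogenase and TCA cycle list, 38.5% for fatty acid oxidation, 50.0% for cholesterol and fatty acid synthesis, 61.3% for oxidative phosphorylation and 70.0% for cobalamin metabolism. The mitochondrial ribosome kept 16 of 31 (percentile 3.84) against 31 by overlap, and mitochondrial DNA expression and import 5 of 13 (percentile 2.09) against 13. Mmachc, Ndufb5, Uqcr10, Mrpl34, Rplp2, Cdc45, Nop14, Hspa9, Thap11 and Fdps each lacked a promoter-annotated ERRα-knockdown peak although their control peak was overlapped. After HCFC1 knockdown the annotation count was 13 of 31 for oxidative phosphorylation (percentile 8.63) and 12 of 15 for the aminoacyl-tRNA synthetases (percentile 95.1). The remaining lists lay between percentiles 8.65 and 96.8 after ERRα knockdown and between 9.46 and 86.5 after HCFC1 knockdown.

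Each knockdown list also held peaks with no control counterpart, most of them weak. After ERRα knockdown these were 8857 peaks (40.5% of the list), with a median score of 34, a highest score of 262 and 804 at promoters. The highest lay in the intergenic region near Cfap126 (chromosome 1, 171113675 to 171114416, score 262), and in that near the potassium channel gene Kcng1 (chromosome 2, 168280608 to 168282037, score 218). Peaks followed in intron 2 of the homeobox gene Lbx1 (chromosome 19, 45233553 to 45236163, score 210), in intron 1 of Pax2, which encodes a paired-box factor of kidney development (chromosome 19, 44750122 to 44751200, score 208), and at the promoter of Trappc12 (chromosome 12, 28750069 to 28750738, score 198). Hmx2 (exon 2, 190), Tns3 (intron 1, 189), Zranb3 (intron 1, 187), Efcc1 (exon 2, 184) and Csgalnact2 (promoter, 180) completed the 10 highest. Kcng1, Lbx1, Pax2, Hmx2, Tns3 and Zranb3 had an overlapping peak after HCFC1 knockdown as well. In the list restricted to a score of at least 100, 180 of 7994 ERRα-knockdown peaks (2.25%) had no control counterpart, and with reciprocal overlap of at least 50% in the full list 58.3% had none. With the score limit in the control list too, the share without a counterpart was far higher, as given with the alternatives below.

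After HCFC1 knockdown 4297 peaks (34.1% of the list) had no control counterpart, with a median score of 27 and 325 at promoters. The share was 66.2% with reciprocal overlap of at least 50%, 62.0% with peak centres within 200 bp and 1.39% among peaks with a score of at least 100. With that limit in the control list too, it was higher than 1.39%. The highest, with a score of 1626, was a narrow intergenic peak near 4930517M08Rik (chromosome 17, 4626222 to 4626544), absent from the ERRα-knockdown list too. The next were in an intron of Gm3704 (chromosome 5, 151417637 to 151418433, score 229), between genes near Alox5ap (chromosome 5, 149247970 to 149248225, score 218), in intron 1 of the homeobox gene Nkx2-4 (chromosome 2, 147083890 to 147085463, score 198) and in the 5′ UTR of Lbx1 (chromosome 19, 45234592 to 45236067, score 180). An intergenic peak near the imprinted RNA gene H19 (chromosome 7, 142579931 to 142581028) scored 173. Nbea (147), Sall3 (142), Malt1 (138) and Pisd-ps1 (135) followed. Among the 4297 peaks, 1222 (28.4%) were overlapped in the ERRα-knockdown list, and 920 of the 8857 ERRα-knockdown peaks (10.4%) were overlapped in the HCFC1-knockdown list.

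The last comparison asked whether the same control peaks went missing in both knockdowns. In all, 20925 control peaks (57.9%) were in neither knockdown list, 7496 were in both, 7177 in the ERRα-knockdown list only and 549 in the HCFC1-knockdown list only. At promoters 3158 were in both, 1945 in the ERRα-knockdown list only, 60 in the HCFC1-knockdown list only and 624 in neither. Independent loss would leave 16695 control peaks in neither list, and independent loss within 20 bins of control score 19484 (central 95% of draws 19437 to 19530), so the observed count was 1.07 times the score-matched value. This ratio was 1.01 with reciprocal overlap of at least 50% and 3.21 with a control score of at least 100, a limit chosen after the data were seen. With that limit in every list the ratio was much lower, as given with the alternatives below. Among control promoter peaks with such a score, only those of Tm7sf2 and Sh3tc1 were in neither list. For promoter peaks alone, the score-matched value was 549 (532 to 565) against 624 observed. Part of the excess may come from the control list that both comparisons share.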

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

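The score limit of 100, the score bins split by promoter annotation, chromosome or width, and the overlap count of kept genes were chosen after the data were seen; the other alternatives were planned. The values are shares and ratios without a sign, and 89 of the 103 that answer a comparison left their 95% counting interval. Tighter overlap rules lower the shared counts by construction, and score limits remove weak peaks; apart from that, the cause was not tested. The scale of the score is not stated, so a limit of 100 need not mean the same in every list. Restriction to chromosomes 1 to 19 and X moved none of the values. With reciprocal overlap of at least 50%, the ERRα-knockdown list kept 25.2% of control peaks and 63.9% of control promoter peaks, and the HCFC1-knockdown list 11.8% and 31.4%. Without a control peak were 58.3% of ERRα-knockdown peaks and 66.2% of HCFC1-knockdown peaks, and 71.3% of control peaks were in neither knockdown list, 1.01 times the score-matched value. With peak centres within 200 bp, the ERRα-knockdown list kept 22.1% of control and 49.6% of control promoter peaks, and the HCFC1-knockdown list 13.3% and 32.8%. Without a control peak were 63.5% and 62.0% of the ERRα-knockdown and HCFC1-knockdown peaks, and 72.4% of control peaks were in neither list, a ratio of 1.03. In the higher-scoring 50% of the query list, the ERRα-knockdown list kept 62.9% of control and 95.3% of control promoter peaks, and the HCFC1-knockdown list 39.0% and 65.1%. Without a control peak were 9.83% and 16.5% of the knockdown peaks, in the same order, and 35.8% of control peaks were in neither list, a ratio of 1.17. In the higher-scoring 50% of every list, the kept shares were 54.4% and 89.1% for ERRα knockdown and 27.0% and 48.4% for HCFC1 knockdown, 18.0% and 21.7% of the knockdown peaks had no control peak, and 44.4% of control peaks were in neither list. There the promoter shares were 26.0% of control, 38.7% of ERRα-knockdown and 38.8% of HCFC1-knockdown peaks, 19.7% of protein-coding genes had a control promoter peak, and 33.9% of control promoter genes were kept by annotation after HCFC1 knockdown. With lists of equal length, the kept shares were 71.8% and 95.4% for ERRα knockdown and 51.1% and 70.0% for HCFC1 knockdown, 32.1% and 45.7% of the knockdown peaks had no control peak, and 26.3% of control peaks were in neither list, a ratio of 1.26. Promoters were then 33.2% of control and 35.6% of ERRα-knockdown peaks, 17.7% of protein-coding genes had a control promoter peak, and 63.1% and 48.4% of control promoter genes were kept by annotation after ERRα and HCFC1 knockdown. With peaks within 500 bp merged, the kept shares were 39.5% and 89.6% for ERRα knockdown and 23.0% and 59.5% for HCFC1 knockdown, 37.9% of ERRα-knockdown peaks had no control peak, and 59.0% of control peaks were in neither list, a ratio of 1.07. With a score of at least 100 in the query list, the kept shares were 96.4% and 99.9% for ERRα knockdown and 78.9% and 83.4% for HCFC1 knockdown, 2.25% and 1.39% of the knockdown peaks had no control peak, and 3.44% of control peaks were in neither list, a ratio of 3.21. With that limit in every list, the kept shares were 92.2% and 97.4% for ERRα knockdown and 26.7% and 32.0% for HCFC1 knockdown, 33.0% and 9.19% of the knockdown peaks had no control peak, and 7.63% of control peaks were in neither list, a ratio of 1.09. Score bins split by promoter annotation gave a ratio of 1.07, by promoter annotation and chromosome 1.06, and by peak width 1.06. With promoters defined as at most 1000 bp from a transcription start, they made up 31.4% of control, 50.6% of ERRα-knockdown and 56.8% of HCFC1-knockdown peaks, 44.2% of protein-coding genes had a control promoter peak, and 85.7% and 57.0% of control promoter genes were kept after ERRα and HCFC1 knockdown. At 5000 bp the shares were 49.6%, 76.6% and 77.5% of peaks, 49.3% of protein-coding genes, and 85.9% and 58.4% of control promoter genes kept. By overlap of the control promoter peak, 89.0% and 57.1% of control promoter genes were kept. Of the values for single lists and named peaks, 151 of 656 left their interval or, for a named peak, changed between present and absent; the named control peaks made up 29 of these, out of 358 values. The planned motif search and its alternative windows were not run, since no genome sequence was used here. No paired analysis was possible because each condition had 1 HCFC1 library. Depth is unknown, so a missing peak may be a peak under the calling limit: among control promoter peaks the share kept after HCFC1 knockdown went from 55.6% in the full lists to 83.4% for scores of at least 100.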

Other observations

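All tests in this part were chosen after the results they bear on had been seen. Peaks shared by the knockdown lists and absent from control included some near developmental regulators. Apart from Lbx1, Pax2 and Hmx2, peaks were at Nkx2-4 (intron, score 170), the haematopoietic factor gene Gata2 (promoter, 148), the heart and limb regulator Hand2 (exon, 139), Dmrta2 (exon, 137), the neuronal factor gene Tbr1 (exon, 136) and Shox2 (promoter, 109). A list of 51 developmental transcription factor families was drawn up after 11 of its genes had been seen among such peaks, so the tests left out every peak nearest to a gene of their families. For the remaining 39 families the share was 2.1% (19 of 904, 1.27 to 3.26%) against 0.783% (0.601 to 1.00%) of the peaks found after ERRα knockdown alone. In the HCFC1-knockdown list it was 2.07% (25 of 1205, 1.35 to 3.05%) against 1.08% (0.742 to 1.51%), with intervals that overlap, so the nearness is not settled there.

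A candidate explanation is the higher score of peaks found in both lists, or their shorter distance to a transcription start. In the ERRα-knockdown list, the 19 observed lay above the central 95% of 10000 draws matched on score (4 to 14, highest 21), distance (4 to 16, highest 20) or both (5 to 16), but 11, 21 and 35 draws reached it, so neither is excluded. In the HCFC1-knockdown list, 243 of 10000 draws matched on score (11 to 24, highest 31), 2361 matched on distance (15 to 29, highest 36) and 3958 matched on both reached the 25 observed, so distance alone could account for that count. With all 51 families, which counts the genes that prompted the list, 0 of 10000 draws matched on score, distance or both reached the 35 observed after ERRα knockdown, and 6, 108 and 608 reached the 42 observed after HCFC1 knockdown. The hypothesis that either knockdown moves HCFC1 toward silent developmental loci has no test here, since the control list may hold weaker signal under the calling limit at the same places.

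The strongest control peaks found in neither knockdown list were named after their values were seen. The strongest, on the unplaced contig GL456359 (18192 to 20594, score 3743), had no annotation. The next, none at a promoter, lay on chromosome 2 (98666707 to 98667216, score 3667), 1199304 bp from the nearest transcription start, near Zfp958 on chromosome 8 (4677201 to 4679335, score 3518), in an intron of Gm21119 (chromosome 8, 19784442 to 19785286, score 3250) and on chromosome X near 4933407K13Rik (75672749 to 75674991, score 2762). No explanation was tested for them.

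Of the 2265 control promoter genes without a promoter-annotated peak after ERRα knockdown, 74.9% (1696) had their control promoter peak overlapped by an ERRα-knockdown peak. Because 4952 of all 5567 control promoter genes were overlapped, most of any 2265 of them had to be. The share therefore cannot decide whether wider peaks, with centres outside the promoter, explain the low percentiles of ribosomal and mitochondrial lists by annotation. For the 569 genes with no overlapping peak, 99.5% had a control score under the median of 100, which is consistent with peaks near the calling limit. Complete loss at the strongest promoters after ERRα knockdown is argued against by 0 of 1927 promoter peaks missing in the highest of 10 score bins. A partial change in HCFC1 signal at promoters, or loss of true weak sites, stays open. The lists give a score for each peak, but its scale is not stated and scores were not compared between lists.

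Control promoter peaks were kept less often after HCFC1 knockdown on chromosomes 9 (34.6%), 12 (38.8%), 14 (37.1%) and X (30.0%) than on the others together (58.5%). Lower control scores do not account for this, since 258 of 723 peaks were kept there and the lowest of 10000 score-matched draws was 311. Chromosome-wide differences in read or copy number could contribute: the 5 chromosomes with the fewest control intergenic peaks per Mb (9, 12, 14, 16 and X, 0.416 to 1.26 per Mb, against 2.93 to 11.3 on the other 15) were the 5 with the lowest retention relative to score. Relative to score, retention on those 5 was between -17.2 and -4.33 percentage points after HCFC1 knockdown and between 2.81 and 8.41 after ERRα knockdown, while the other 15 spanned -3.81 to 5.93 and -4.16 to 2.44. No copy number was measured here, no biological explanation was tested, and chromosomes are not replicates.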
